A study of Mus musculus with 6 samples.

How the data were processed

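RNA of hand-picked pancreatic islets from C57BL6/J mice was sequenced after a TruSeq transcriptome library preparation, per the labels' protocols. The islets were freed by an enzyme solution injected into the bile duct. The samples used here were 3 from pregnant mice at gestational day 14.5 and 3 from nonpregnant mice, grouped by their labels. The design text speaks of 5 animals per group. Nothing in the labels says whether each sample came from 1 animal. What spread the authors' p-values measure is not known, because their test is not described in the sources used here. The p-values computed here compare genes with other genes and hold no spread between samples.

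Reads were aligned and counted per gene with TopHat2 2.0.12, TopHat, Bowtie and HTSeq 0.5.3p3 on the mouse build GRCm38, per the submitters' processing notes. Whether counting used strand, and whether libraries were scaled before averaging, is not given in the sources used here. Each line of the authors' deposited table gives a gene with a mean read count for each group, per the file headers, and no value per library. Some genes stand on more than 1 line. Beside these means the authors deposited a fold change, which is a linear ratio of pregnant over nonpregnant. The log2 of that ratio was also deposited by the authors. The same table holds the authors' p-value and its adjusted form (FDR) for each gene. The tool behind that test is not given in the sources used here. A length column was not used, because it showed a Spearman rho of 0.00875 across genes with annotated exon length and differed between lines in 21 of 21 repeated genes.

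The columns were checked against each other. Recomputed Benjamini-Hochberg values differed from the deposited adjusted p-values by at most 0.00203 and gave the same count of 2337 genes under 0.05. The deposited log2 ratio exceeded the log2 of the ratio of the read means by a median of 0.04 (SD 0.00127 across 10102 genes with over 500 mean reads in both groups), a factor of 1.02 that was the same for nearly every gene. For genes under 10 mean reads, a pseudocount of 1 fitted the log2 ratio within 0.005 in 100% of genes, against 88.0% with a pseudocount of 0. Pseudocounts of 0.5 and 2 fitted 98.2% and 73.1% of these genes. Fold changes of low genes are therefore on a scale of mean plus 1 and understate large changes. In 311 genes both means were rounded to 0, and the log2 ratios of 311 of them fitted means over 3 libraries within 0.02, against 28 for means over 5 libraries.

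The table held 19940 genes by Ensembl ID. Of these, 21 stood on more than 1 line with identical reads, log2 ratio and p-values and were counted once, and 76 had no symbol. Gene IDs were matched to the GENCODE M21 annotation of GRCm38, which contained 19256 of them (96.6%) and supplied coordinates, strands and exon lengths. The authors' mean reads summed to 87654449 in the pregnant group and 84493872 in the nonpregnant group. The depth of single libraries was not analysed here.

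The design fixed before the data were examined assumed counts per library. It named edgeR's quasi-likelihood test as the test, with DESeq2, limma voom and refits without single libraries as alternatives. None of these could be run on group means, so the authors' deposited adjusted p under 0.05 was used for genes. For 30 gene lists, fixed before the data were examined, the planned camera test was replaced by its form for precomputed statistics, cameraPR of limma 3.58.1 in R 4.3.3. It compared the ranks of the signed normal deviate of the deposited p-value between list members and all other genes, with a preset inter-gene correlation of 0.01. It ran on 15682 genes with a mean of at least 10 reads over both groups, and Benjamini-Hochberg adjustment covered the 30 lists. An estimated correlation needs values per library and was not computed, so it is not known which list calls would hold with one. Members of a list were also counted as higher or lower by the deposited adjusted p over all genes, and by Benjamini-Hochberg values adjusted over the list alone. Tested on simulated data with the 15682 genes and 20 draws, cameraPR called 100% of 6 lists shifted by 1 SD and 1.04% of lists without a shift. The simulated genes were independent, so neither rate covers lists whose members vary together. The 6 shifted lists were the largest, so the 100% does not carry over to smaller lists. The remaining calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

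Genes were named by a rule fixed before the data were examined. It took the 15 largest rises and 10 largest falls among genes with a deposited adjusted p under 0.05, an average log2 CPM of at least 2 and a symbol that is not a clone or model name. It also took a fixed set of 16 genes, up to 4 members with the smallest p in each list described, and the 5 genes with the most reads. A further criterion, that every pregnant library lie on one side of every nonpregnant library, could not be evaluated. Some genes that the rule takes are not reported here. Shares of reads were computed from the sums of the authors' means and have no error.

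Alternatives recomputed here were stricter thresholds, other filters on low reads, removal of the acinar list, other forms of the list test, other scalings and random lists matched on annotated exon length and mean reads. Sequence shared by adjacent genes was 31 bases in common between their GENCODE M21 transcripts on either strand. The adjacency and matched-list tests of the closing part were tested on simulated data with 15384 genes and 40 draws. Chance placement was called in 5% of draws and 60 planted pairs in 100%. Matched lists without a shift were called in 2.5% and lists shifted by 0.3 in 100%. For sets drawn from 204 genes, the test of fold against p called 2.5% of unshifted sets and 97.5% of sets multiplied by 2. Neither rate covers sets whose genes vary together. In 40 draws of random sequences of 2000 bases, the search for shared sequence called 100% of pairs with 31 planted bases on either strand and 0% of pairs without them.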

Results

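Gene expression was measured by RNA sequencing in pancreatic islets of pregnant mice at gestational day 14.5 and of nonpregnant mice, with 3 samples in each group. Islets are the hormone-secreting cell clusters of the pancreas, in which beta cells make insulin, alpha cells glucagon, delta cells somatostatin and PP cells pancreatic polypeptide. The question was which islet transcripts differ in pregnancy, when the demand for insulin is high. All values below come from group means and the authors' own test, so no spread between libraries can be given. The authors' mean reads per gene summed to 87654449 for the pregnant group and 84493872 for the nonpregnant group.

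Tph1, which encodes the rate-limiting enzyme of serotonin synthesis outside the brain, showed the largest rise in the pregnant islets. In the authors' deposited table its authors' mean went from 11 reads in nonpregnant to 22212 reads in pregnant islets, a 1848-fold rise with p listed as 0. Genes of cell division rose together, with Mki67, the Ki-67 proliferation antigen, up 5.67-fold in the authors' deposited table (adjusted p = 2.61e-20). Cish, a feedback inhibitor of cytokine receptor signalling, and the granule protein gene Chgb rose, while genes of cholesterol synthesis and uptake, the circadian clock and alpha cells were lower as groups. Digestive enzyme genes of acinar cells, the exocrine cells that surround islets, were also higher in the pregnant mean, and their share of all mean reads was 1.79% against 0.142%.

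Of 19940 genes, 2337 (11.7%) passed an adjusted p under 0.05 in the authors' deposited table. Among them 1510 (64.6%) were higher and 827 lower in pregnancy. The median fold change in the authors' deposited table was 1.55 for the higher genes and 0.72 for the lower ones. A log2 ratio of at least 1 was reached by 511 higher genes, and a log2 ratio of -1 or below by 81 lower genes. At 3 or more the higher genes numbered 127, and 0 genes fell by as much. At an unadjusted p under 0.05 there were 4418 genes. The median log2 ratio over the 15682 genes with at least 10 mean reads was -0.01.

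**Figure D1:**
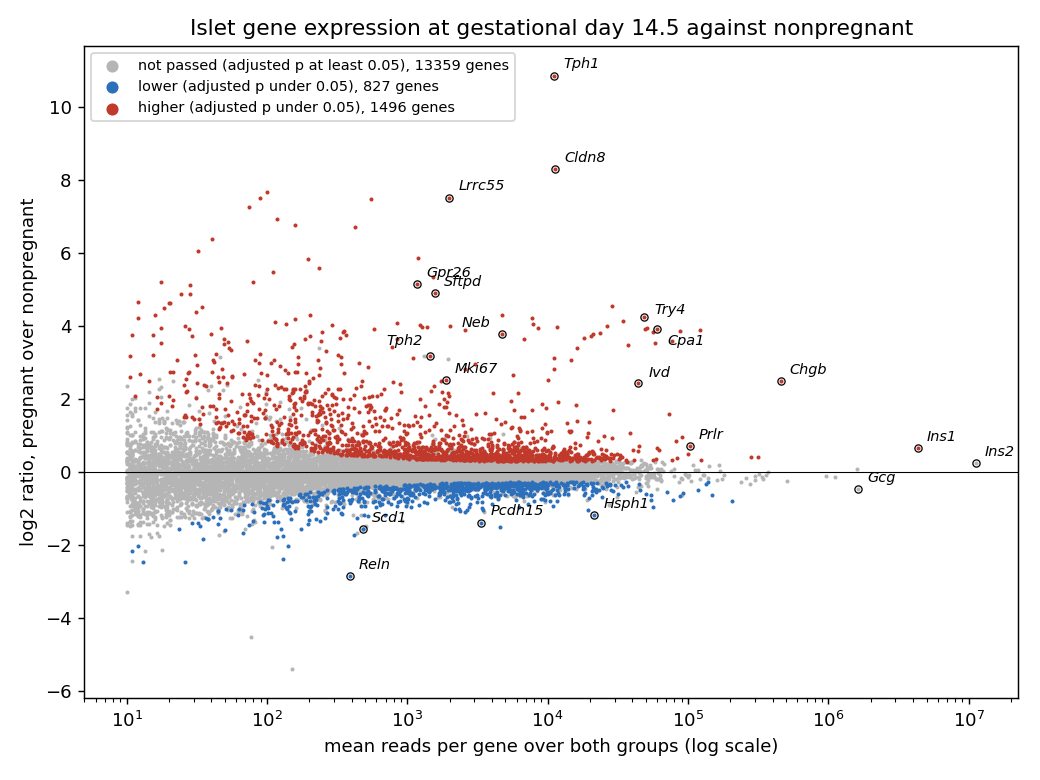
Each point is a gene with at least 10 mean reads over both groups, with mean reads on a log scale across and the log2 ratio of pregnant over nonpregnant islets upward, from the authors' deposited table. Red points passed an adjusted p under 0.05 as higher and blue points as lower; Tph1 stands at a log2 ratio of 10.85, Cldn8 at 8.29 and Reln at -2.87.

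After Tph1, the largest rises by the naming rule included Cldn8, a claudin of tight junctions, and Lrrc55, which encodes an auxiliary subunit of BK potassium channels. The authors' deposited table gave fold changes of 313 and 182 for these genes, with adjusted p-values of 2.58e-41 and 3.67e-15. Tph1 (ENSMUSG00000040046) lies on the minus strand of chromosome 7 at 46644641 to 46672537 of GRCm38. Cldn8 (ENSMUSG00000050520) lies on the minus strand of chromosome 16 at 88560828 to 88563183, and Lrrc55 (ENSMUSG00000075224) on the minus strand of chromosome 2 at 85162334 to 85197197. Crispld2, Dnahc8, an axonemal dynein, the orphan receptor gene Gpr26, and Sftpd, which encodes surfactant protein D, rose 58.1-fold, 40.5-fold, 35.3-fold and 29.6-fold in the authors' deposited table. In nonpregnant islets Tph1 had an authors' mean of 11 reads, Lrrc55 21 and Crispld2 40 in the authors' deposited table, so those folds rest on few nonpregnant reads. Lrrc55, Crispld2, Dnahc8, Gpr26 and Klk1 overlap the span of genes on the opposite strand, so their reads are uncertain where counting ignored strand. Of the 15 named rises, 5 were in the acinar list: Try5, Pnliprp2, Try4, Gp2 and Pnliprp1, at 17.5-fold to 23.4-fold in the authors' deposited table. The trypsin genes Try4 and Try5 are close paralogs, so the split of reads between them is uncertain. Serpini2 and Klk1, a kallikrein, were also among the 15, at 16.9-fold and 16.4-fold in the authors' deposited table, both below these 5 acinar members.

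The 10 largest falls by the same rule were smaller. Reln, which encodes the extracellular protein reelin, fell to 0.14 of its nonpregnant level in the authors' deposited table (adjusted p = 5.14e-17). Ltbp2, a latent TGF-beta binding protein, the desaturase gene Scd1, which makes monounsaturated fatty acids, Cib3 and the imprinted gene Zim1 fell to between 0.3 and 0.35 in the authors' deposited table. Pcdh15, a protocadherin, Hist2h4, a histone H4 gene, Dapl1, the heat shock gene Hsph1 and Vsnl1, a neuronal calcium sensor, fell to between 0.38 and 0.44 in the authors' deposited table. Reln and Ltbp2 overlap the span of genes on the opposite strand, with the same limit. Histone H4 genes are nearly identical to each other, which makes the value for Hist2h4 uncertain.

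Genes of serotonin synthesis and handling did not pass as a list. Of 15 measured members, 4 rose and 0 fell over all genes, and 4 rose and 0 fell adjusted over the list alone. Besides Tph1, these were Tph2, the neuronal tryptophan hydroxylase, Slc18a1, a vesicular monoamine transporter, and Ddc, the decarboxylase that completes serotonin synthesis. Their fold changes in the authors' deposited table were 8.95, 1.72 and 1.25. The rank form of the test gave an adjusted p of 0.1 (cameraPR), while its parametric form, chosen after seeing the data, passed at 4.43e-08. The parametric form works on the mean deviate, in which the p listed as 0 for Tph1 entered at a capped value. It was not run without Tph1, and 11 of the 15 members did not pass over all genes. In pregnant islets the authors' mean was 22212 reads for Tph1 and 2583 for Tph2 in the authors' deposited table.

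Prolactin and growth hormone receptor signalling did not pass as a list either. Among 18 members, 6 rose and 2 fell over all genes, with 8 higher and 2 lower adjusted over the list alone (cameraPR adjusted p = 0.116; parametric form 1.36e-05). Its median log2 ratio of 0.15 lay above the central 95% of 10000 random lists matched on annotated exon length and mean reads (-0.15 to 0.10), whereas the serotonin median of 0.09 lay inside its own (-0.17 to 0.18). With scaling to total mean reads, also chosen after seeing the data, these medians were 0.07 and 0.00. This comparison was chosen after seeing the data and takes genes as independent, so its ranges are narrow. Cish and Socs2, feedback inhibitors induced by STAT5, rose 5.72-fold and 2.81-fold in the authors' deposited table. Cish overlaps the span of Gm17040 on the opposite strand, so its reads are uncertain where counting ignored strand. Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, rose 7.76-fold, and Foxm1, a transcription factor of the cell cycle, rose 3.47-fold in the authors' deposited table. Prlr, the prolactin receptor, rose 1.63-fold in the authors' deposited table (adjusted p = 0.0104). The cell cycle inhibitor gene Cdkn1b fell to 0.78 in the authors' deposited table (adjusted p = 0.0095). Men1, the gene of menin, and Bcl6, a transcriptional repressor, did not pass, at ratios of 1.06 and 1.51 in the authors' deposited table (adjusted p = 0.809 and 0.0741).

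A list of 19 genes known to respond to pregnancy in islets rose in full, with 19 of 19 higher over all genes and 19 higher adjusted over the list alone (median log2 ratio 2.52, cameraPR adjusted p = 5.49e-11). The list was compiled from general knowledge of islets in pregnancy, which may include results from these libraries, so it is not independent evidence of its direction, and 12 of its members stand in other lists. Neb, the gene of the muscle protein nebulin, rose 13.6-fold, Matn2, a matrix protein gene, 8.26-fold and Lonrf3 8.71-fold in the authors' deposited table.

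Cell division genes were higher as lists. All 30 measured mitosis genes rose over all genes, and 30 adjusted over the list alone, with a median log2 ratio of 2.06 (cameraPR adjusted p = 1.34e-14). Melk rose 7.66-fold, the mitotic kinases Aurkb and Bub1 6.6-fold and 6.51-fold, and the spindle motor gene Kif11 3.57-fold in the authors' deposited table. Of 31 DNA replication genes, 23 rose and 0 fell over all genes, with 26 higher and 1 lower adjusted over the list alone (median log2 ratio 0.86, cameraPR adjusted p = 1.34e-10). Uhrf1, which maintains DNA methylation at replication, rose 7.71-fold, the licensing factor Cdc6 5.6-fold, the ribonucleotide reductase subunit Rrm2 4.08-fold and the helicase subunit Mcm5 3.23-fold in the authors' deposited table. Cell cycle regulators were mixed, with 5 higher and 1 lower of 20 over all genes, and 7 higher and 1 lower adjusted over the list alone (cameraPR adjusted p = 0.0694; parametric form 0.0243). Myc rose 3.21-fold, the inhibitor gene Cdkn2c 2.45-fold and E2f1 1.69-fold in the authors' deposited table. Microtubule genes did not pass as a list (4 higher and 0 lower of 16 by both adjustments, the second adjusted over the list alone, cameraPR adjusted p = 0.13). Stmn1, which destabilises microtubules, rose 3.95-fold in the authors' deposited table, and the tubulin genes Tuba1c, Tubb5 and Tubg1 rose 1.25-fold to 1.4-fold in the authors' deposited table.

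**Figure D2:**
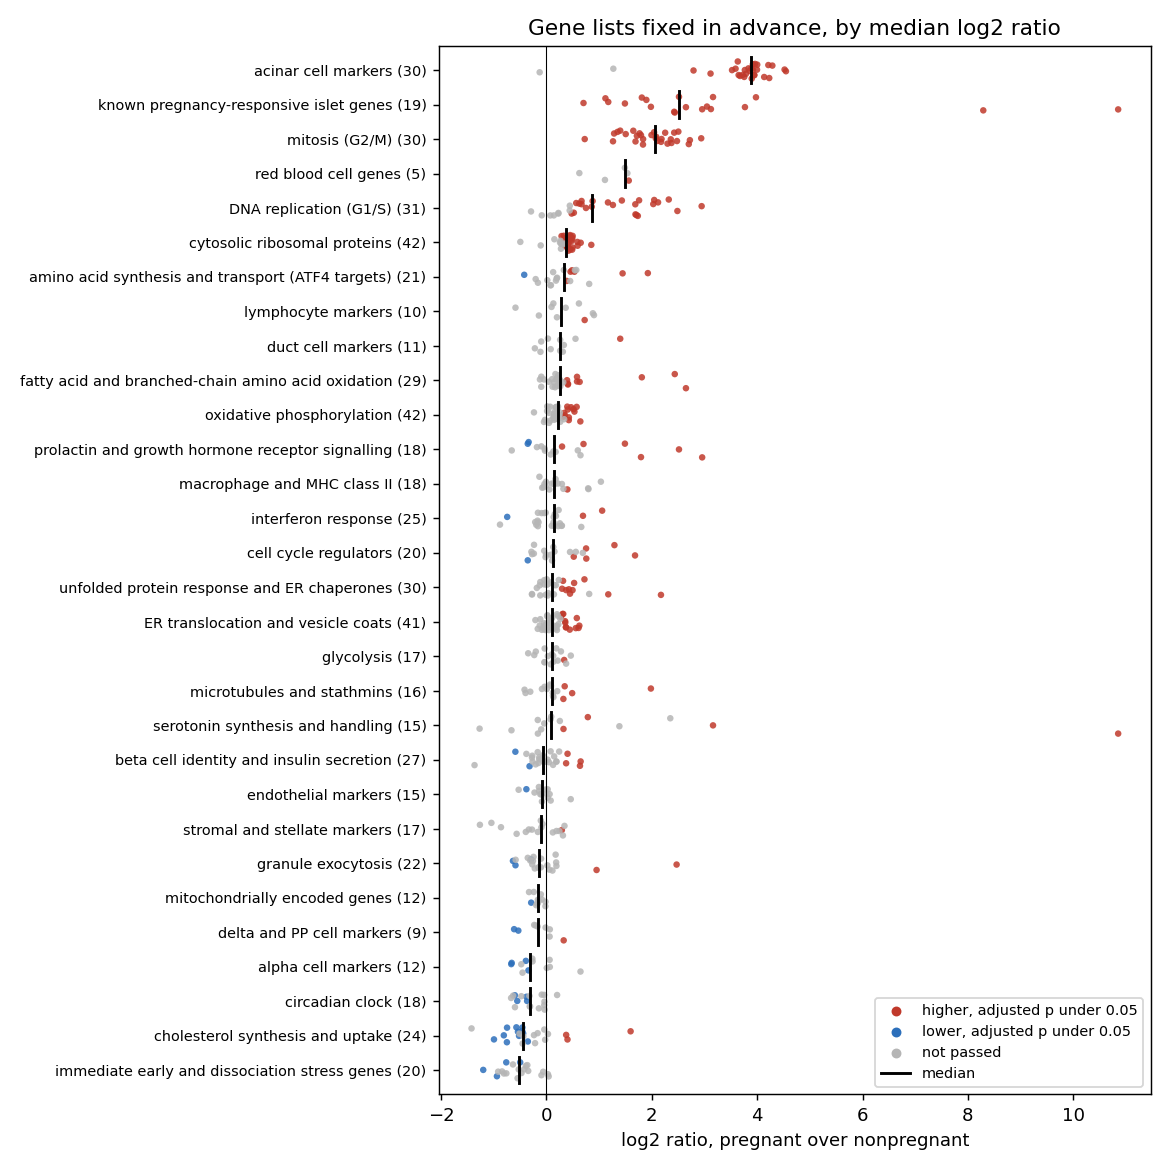
Each point is a measured member of a gene list fixed in advance, placed by its log2 ratio of pregnant over nonpregnant islets from the authors' deposited table, with the number of measured members in brackets and a bar at the list median. Red members were higher and blue members lower at an adjusted p under 0.05; the acinar list has the highest median (3.88) and the immediate early and stress list the lowest (-0.51).

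Beta cell genes did not pass as a list. Of 27 members, 4 rose and 2 fell over all genes, and 4 rose and 4 fell adjusted over the list alone (median log2 ratio -0.06, cameraPR adjusted p = 0.635). That median lay just below the range of matched lists (-0.05 to 0.18) and was -0.14 with scaling to total mean reads, both chosen after seeing the data. Ins1 rose 1.55-fold in the authors' deposited table (adjusted p = 1.61e-08), whereas Ins2 stood at 1.18-fold without passing (adjusted p = 0.288). The 2 insulin genes are close paralogs, so reads could be split between them. Pcsk1, a proinsulin-processing convertase, rose 1.57-fold and the receptor gene Glp1r 1.3-fold, while Slc30a8, the zinc transporter of insulin granules, fell to 0.66 in the authors' deposited table. Iapp, the gene of islet amyloid polypeptide, was at 1.06-fold in the authors' deposited table (adjusted p = 0.787). Alpha cell genes were lower as a list, with 0 higher and 4 lower of 12 over all genes, and 1 higher and 5 lower adjusted over the list alone (median log2 ratio -0.30, cameraPR adjusted p = 0.0307). Ttr and Dpp10 fell to 0.63, Gc to 0.76 and Irx2, an alpha cell transcription factor, to 0.79 in the authors' deposited table. Gcg, the glucagon gene, was at 0.72 and did not pass in the authors' deposited table (adjusted p = 0.0772). Reads of whole islets cannot tell a smaller share of alpha cells from lower expression per cell. Delta and PP cell genes did not pass as a list (1 higher and 2 lower of 9 by both adjustments, the second adjusted over the list alone, cameraPR adjusted p = 0.168). Hhex, a delta cell transcription factor, fell to 0.69 and the receptor gene Crhr2 fell to 0.65 in the authors' deposited table, while Ptprz1 stood at 0.85 (adjusted p = 0.264). Sst and Ppy were at 0.87 and 0.89 in the authors' deposited table and did not pass.

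By share of summed mean reads, the 2 insulin genes took 19.6% in pregnant and 16.4% in nonpregnant islets. Gcg took 1.53% and 2.26%, Sst 0.355% and 0.435%, Ppy 0.275% and 0.328%, and Iapp 1.84% and 1.85%, in the same order. Ins2, Ins1, Gcg, Iapp and Chga were the 5 genes with the most reads and together took 24.2% and 21.9%. These shares come from 1 mean per group and have no error, so whether they differ by more than the spread between libraries is not known.

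Chgb, which encodes the granule matrix protein chromogranin B, rose 5.54-fold in the authors' deposited table (adjusted p = 9.05e-33), and its share of mean reads was 0.879% against 0.169%. Chga, the gene of chromogranin A, stood at 0.9 in the authors' deposited table (adjusted p = 0.426). The granule exocytosis list as a whole did not pass, with 2 higher and 3 lower of 22 over all genes, and 2 higher and 7 lower adjusted over the list alone (cameraPR adjusted p = 0.1). Its median log2 ratio of -0.15 lay below the range of matched lists (-0.10 to 0.15) and was -0.24 with scaling to total mean reads, both chosen after seeing the data. Rab3d, a small GTPase of secretory granules, rose 1.94-fold, while the calcium channel gene Cacna1c fell to 0.64 and the priming factor gene Unc13a to 0.67 in the authors' deposited table.

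**Figure D3:**
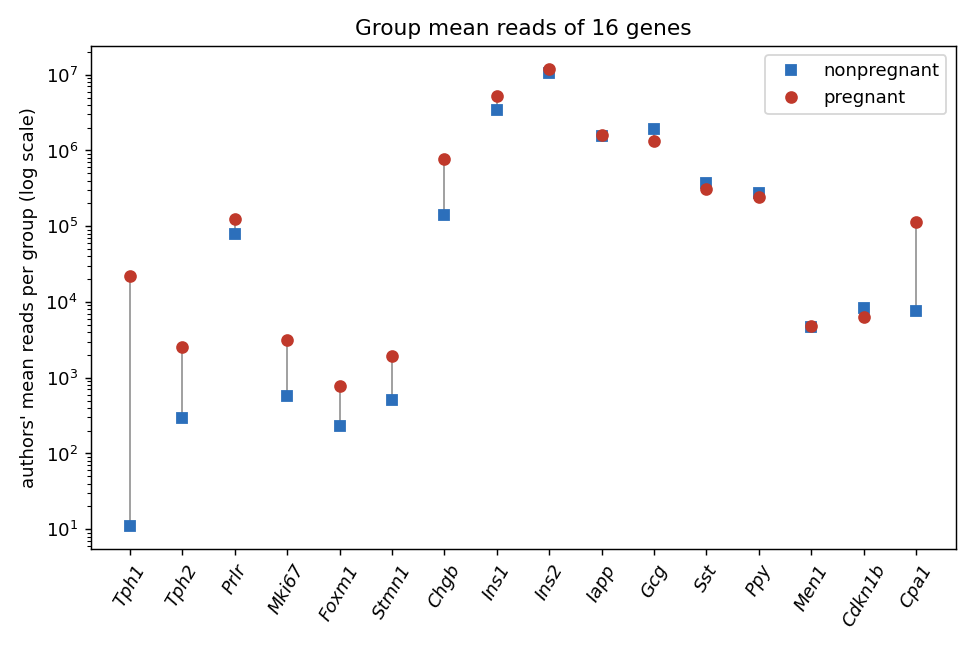
Group mean reads of 16 genes on a log scale, with squares for nonpregnant and circles for pregnant islets, each point the authors' mean from the authors' deposited table with no error available. Tph1 spans 11 to 22212 reads and Chgb 142625 to 770721 reads, while Iapp and Men1 overlap.

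Lists of the secretory pathway passed the rank test as higher, with small medians. Of 41 genes of ER translocation and vesicle coats, 12 rose and 0 fell over all genes, and 13 rose and 0 fell adjusted over the list alone (median log2 ratio 0.11, cameraPR adjusted p = 0.0006). Sec61b and Ssr4 of the translocon, Tmed3 of vesicle transport and the signal peptidase gene Spcs1 rose 1.47-fold to 1.54-fold in the authors' deposited table. Of 30 genes of the unfolded protein response, 10 rose and 0 fell over all genes, and 11 rose and 1 fell adjusted over the list alone (median log2 ratio 0.12, cameraPR adjusted p = 0.0154). Scaling to total mean reads, chosen after seeing the data, left these medians at 0.02 and 0.03. Both unscaled medians lay inside the central 95% of 10000 random lists matched on annotated exon length and mean reads (-0.04 to 0.12 and -0.02 to 0.17), a comparison also chosen after seeing the data. Derl3 and Edem1, of ER-associated degradation, rose 4.51-fold and 1.65-fold, and the ER protein genes Fkbp11 and Sdf2l1 2.26-fold and 1.44-fold in the authors' deposited table. The acinar share of mean reads was 1.79% against 0.142% in the same comparison, and acinar cells are rich in secretory pathway transcripts. ATF4 target genes of amino acid synthesis and transport included 6 higher and 1 lower of 21 over all genes, and 6 higher and 1 lower adjusted over the list alone (median log2 ratio 0.33, cameraPR adjusted p = 0.00464). Nupr1, a stress-induced nuclear protein gene, rose 3.8-fold, the proline synthesis genes Pycr1 and Aldh18a1 rose 2.73-fold and 1.37-fold, and Shmt2 of one-carbon metabolism rose 1.31-fold in the authors' deposited table.

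Cytosolic ribosomal protein genes rose together by a small amount, with 33 higher and 0 lower of 42 over all genes, and 39 higher and 1 lower adjusted over the list alone (median log2 ratio 0.38, cameraPR adjusted p = 5.04e-13). Rplp1 rose 1.81-fold, Rplp0 1.5-fold and Rpl3 and Rpl32 1.41-fold in the authors' deposited table. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Nuclear genes of oxidative phosphorylation were higher, with 12 higher and 0 lower of 42 over all genes, and 16 higher and 0 lower adjusted over the list alone (median log2 ratio 0.22, cameraPR adjusted p = 5.48e-08). That median lay just above the central 95% of lists matched on exon length and mean reads (0.06 to 0.21), and scaling to total mean reads left it at 0.13, both chosen after seeing the data. Ndufa4, Uqcrq, Ndufb9 and Cox7b, of respiratory complexes, rose 1.43-fold to 1.56-fold in the authors' deposited table. The 12 mitochondrially encoded genes went the other way as a list (median log2 ratio -0.16, or -0.25 scaled to total mean reads, cameraPR adjusted p = 0.00483), with 0 higher and 1 lower over all genes and 0 higher and 1 lower adjusted over the list alone. Among them mt-Nd2 fell to 0.82 in the authors' deposited table, and mt-Nd5, mt-Nd6 and mt-Nd4 stood at 0.85, 0.87 and 0.8 without passing. Mitochondrially encoded genes took 3.32% of mean reads in pregnant and 3.90% in nonpregnant islets. In fatty acid and branched-chain amino acid oxidation, 9 rose and 0 fell of 29 over all genes, and 15 rose and 0 fell adjusted over the list alone (median log2 ratio 0.25, or 0.16 scaled to total mean reads, cameraPR adjusted p = 3.1e-06). Ehhadh, of peroxisomal beta-oxidation, rose 6.27-fold, Ivd, of leucine breakdown, 5.41-fold, Aass, of lysine breakdown, 3.51-fold and Cpt1a, the entry step of mitochondrial fatty acid oxidation, 1.5-fold in the authors' deposited table. Glycolysis did not pass as a list (1 higher and 0 lower of 17 by both adjustments, the second adjusted over the list alone, cameraPR adjusted p = 0.1). Tpi1 rose 1.26-fold in the authors' deposited table, while Eno1, Aldoa and Slc2a1 stood at 1.16-fold to 1.3-fold and did not pass.

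Cholesterol synthesis and uptake was lower as a list, with 3 higher and 11 lower of 24 over all genes, and 3 higher and 14 lower adjusted over the list alone (median log2 ratio -0.45, cameraPR adjusted p = 0.000219). Among the members that fell, Tm7sf2, a sterol reductase gene, was at 0.6 and Fdps, which encodes farnesyl diphosphate synthase, at 0.69 in the authors' deposited table, both chosen after their values were seen. Dhcr7, the last step of cholesterol synthesis, rose 3.03-fold against the list in the authors' deposited table (adjusted p = 9.75e-27). Circadian clock genes were lower, with 0 higher and 4 lower of 18 over all genes, and 0 higher and 7 lower adjusted over the list alone (median log2 ratio -0.32, cameraPR adjusted p = 0.00051). Per1, Bhlhe41, Cry1 and the repressor gene Ciart, listed as Gm129, fell to between 0.66 and 0.78 in the authors' deposited table. Immediate early and dissociation stress genes were lower, with 0 higher and 4 lower of 20 by both adjustments, the second adjusted over the list alone (median log2 ratio -0.51, cameraPR adjusted p = 0.000305). Hsph1 fell to 0.44, the chaperone gene Hspa1b to 0.52, the transcription factor gene Fos to 0.59 and the nuclear receptor gene Nr4a1 to 0.71 in the authors' deposited table. Time of day at collection and handling of the islets were not compared between the groups here. Whether the clock and stress lists differ with pregnancy itself is therefore not settled. Interferon response genes did not pass as a list (2 higher and 1 lower of 25 by both adjustments, the second adjusted over the list alone, cameraPR adjusted p = 0.238). The gene listed as Gbp6, whose ID is named Gm43302 in GENCODE M21 and which is therefore uncertain, rose 2.08-fold and Oas1a 1.62-fold, Ifi44 fell to 0.6 and Tap1 stood at 1.22-fold without passing in the authors' deposited table.

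Markers of other cell types were examined in the same way. Of 30 measured acinar genes, 28 rose and 0 fell over all genes, and 28 rose and 0 fell adjusted over the list alone (median log2 ratio 3.88, cameraPR adjusted p = 5.49e-11). Cpa1, the gene of carboxypeptidase A1, rose 15.1-fold in the authors' deposited table (adjusted p = 0.0132), from an authors' mean of 7623 to 112362 reads. Reg1 rose 13.6-fold, Try4 18.8-fold and Cuzd1 16-fold in the authors' deposited table, and Prss1 13.5-fold from 1 read. Macrophage and MHC class II genes were higher as a list (1 higher and 0 lower of 18 over all genes, 0 higher and 0 lower adjusted over the list alone, cameraPR adjusted p = 0.0475), a call that ended with the parametric form (0.313) and whose median of 0.15, or 0.06 scaled to total mean reads, lay inside the matched range. Lyz2, the lysozyme gene, rose 1.32-fold, while C1qa, Mrc1 and Itgam stood at 1.73-fold to 2.05-fold without passing in the authors' deposited table. Red blood cell genes were higher (1 higher and 0 lower of 5 over all genes, 2 higher and 0 lower adjusted over the list alone, cameraPR adjusted p = 0.0154), which also ended with the parametric form (0.105). The haemoglobin gene Hbb-b1 rose 2.95-fold, and Hba-a1, Hbb-b2 and Hba-a2 stood at 2.16-fold to 2.9-fold without passing in the authors' deposited table.

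Duct, endothelial, lymphocyte and stromal lists did not pass (cameraPR adjusted p = 0.129, 0.208, 0.339 and 0.733). Over all genes, 1 of 11 duct genes was higher, 1 of 15 endothelial genes lower, 1 of 10 lymphocyte genes higher and 1 of 17 stromal genes higher. Adjusted over the list alone, the counts were 1 higher for duct, 2 lower for endothelial, 1 higher for lymphocyte and 0 for stromal genes. Muc1, a mucin gene, rose 2.64-fold, Lck, a lymphocyte kinase gene, 1.65-fold and Rgs5, a pericyte marker, 1.23-fold in the authors' deposited table, and the endothelial phosphatase gene Ptprb fell to 0.77. Other members with the smallest p did not pass in the authors' deposited table, at 1.2-fold for Spp1, 1.24-fold for Krt18, 1.27-fold for Sparc, 0.69 for Vwf and 0.85 for Robo4.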

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

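Filters, thresholds and the removal of acinar genes or of acinar and mitochondrial genes were fixed before the data were examined, while the parametric and log2-ratio forms of the list test, the scalings, the matched lists and the minimum of 10 reads were chosen after seeing the data. No paired analysis was possible because the deposited table gives 1 mean per group and no column carries a replicate number. The edgeR, DESeq2 and limma voom fits, RLE factors, robust shrinkage, refits without single libraries, an acinar covariate, an estimated correlation, fry, other splits of the samples and permutation tests of shares were not run for the same reason. The 2337 changed genes became 1458 (1021 higher, 437 lower) at an adjusted p under 0.01 and 592 (511 higher, 81 lower) with a log2 ratio of at least 1 in size, both by construction. They became 2448 with a mean CPM of at least 1, 2536 with at least 10 reads and 2306 without acinar genes. With a mean CPM of at least 1, the macrophage and red blood cell lists no longer passed (adjusted p = 0.0904 for each), the red blood cell list then holding 2 genes. In the parametric form these lists stood at 0.313 and 0.105, and the serotonin, prolactin and cell cycle regulator lists passed at 4.43e-08, 1.36e-05 and 0.0243. The lymphocyte list passed at 0.0471 on ranks of the log2 ratio. The cause of these list changes was not tested, and the parametric value for serotonin includes Tph1 at a capped deviate. The other list calls were the same under every form run. Scaling to total mean reads moved every log2 ratio by -0.09 (median of measured genes -0.10), scaling without acinar genes, Ins1 and Ins2 by less than 0.01, and neither turned the median of a passing list. Scaling to total mean reads took the medians for oxidative phosphorylation from 0.22 to 0.13, for fatty acid and branched-chain amino acid oxidation from 0.25 to 0.16, for the macrophage list from 0.15 to 0.06 and for mitochondrially encoded genes from -0.16 to -0.25. Among passing lists, the medians for ER translocation, the unfolded protein response and macrophages lay inside the central 95% of lists matched on exon length and mean reads, and the others outside. Among lists that did not pass, the prolactin, beta cell and granule exocytosis medians lay outside. Without acinar and mitochondrial genes, ratios of pregnant to nonpregnant shares were 1.21 for insulin genes (1.20 with them), 0.682 for Gcg (0.675), 0.826 for Sst (0.817), 0.848 for Ppy (0.838), 1.01 for Iapp (0.994), 5.27 for Chgb (5.21), 1.26 for ribosomal genes (1.25) and 1.12 for the 5 genes with the most reads (1.10). Of the named genes, Vwf passed with either read filter (0.0368 and 0.0413) and Eno1 with the CPM filter (0.0475). Depth per library is unknown, so what depth limits in a single library cannot be said.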

Other observations

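The tests of gene families, of the acinar pattern, of scaling, of divergent or non-overlapping pairs, of pairs without acinar genes, of pairs or families matched on length and of shared sequence were chosen after the result was seen, and those of chance placement, strand, symbol stems and ribosomal gene length before. Families of genes were grouped by the stem of their symbol and tested like the lists. Of 94 families, 9 passed. Zinc finger genes with the stem Zfp were lower by a small amount, with 4 higher and 25 lower of 357 (median log2 ratio -0.15, cameraPR adjusted p = 1.54e-06), and Zbtb genes, which encode another class of zinc finger proteins, were lower with 1 higher and 5 lower of 38 (adjusted p = 0.00567). Ubiquitin-specific protease genes (Usp) were lower with 0 higher and 6 lower of 48 (adjusted p = 0.0249), and RNA-binding motif genes (Rbm) with 2 higher and 3 lower of 32 (adjusted p = 0.0266). Aldehyde dehydrogenase genes (Aldh) were higher with 6 higher and 0 lower of 17 (adjusted p = 0.0107), among them Aldh9a1, named after its values were seen, at 2.52-fold in the authors' deposited table. Mitochondrial ribosomal protein genes (Mrpl, adjusted p = 0.014), cytochrome oxidase genes (Cox, 0.0148) and the Rpl (2.8e-10) and Rps (1.28e-08) families were also higher. The Rpl and Rps families share members with the cytosolic ribosomal list, and Cox with the oxidative phosphorylation list, so they are not separate results. Against random lists matched on exon length and mean reads, the medians of Usp (-0.09, central 95% -0.12 to 0.02), Mrpl (0.14, -0.01 to 0.16) and Cox (0.22, -0.01 to 0.26) lay inside the matched range, so these calls do not stand apart from genes of like length and reads, while Zfp (-0.14 over 342 genes with a length, -0.05 to 0.01) and the other 5 lay outside. Scaling to total mean reads took these medians to -0.18 for Usp, 0.06 for Mrpl, 0.13 for Cox and -0.23 for Zfp.

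The rise of acinar genes, led in reads by Ctrb1 at an authors' mean of 226845 against 15653 reads in the authors' deposited table, had a narrow size and a weak p for its size. Across 27 acinar genes with at least 50 mean reads in nonpregnant islets, the interquartile range of log2 ratios was 0.317 (1.49 across 204 other genes rising by a log2 ratio of at least 2), from -0.13 for the transcription factor gene Bhlha15 to 4.55 for Try5, and Ptf1a, an acinar transcription factor gene, went from 2 to 67 reads in the authors' deposited table. The median ratio of log2 size to the normal deviate of p was 1.16 against 0.438 for the 204 other genes, higher than in 100% of 10000 random sets of them. These sets take genes as independent, whereas the acinar genes moved together. The 100% therefore does not say how often a group of genes that vary together would reach such a median. A candidate explanation is exocrine tissue carried into some libraries of the pregnant group in larger amounts than others, which hand-picking should limit. The p-values bear on it only if they reflect the spread between libraries, which is not known. No member of the acinar list stands in another list, and a true change of acinar genes in pregnancy remains open. A log2 ratio between the 10th and 90th percentile of the rising acinar genes (3.57 to 4.25), with a size over deviate at or above their 10th percentile (1.05), also held for 12 rising genes outside the list, among them Klk1, Serpini2, Pdia2, Tff2, Pla2g1b and Rbpjl, while Derl3, Nupr1, Rab3d and Muc1, named after their values were seen, had ratios of 0.175, 0.254, 0.103 and 0.453.

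Rising genes lay next to each other along chromosomes more often than calls shuffled among genes of like expression. Genes counted as adjacent if they were consecutive among placed genes with at least 10 mean reads. No limit was set on distance, with 143985 bases between Cldn8 and 2310061N02Rik and 3604725 between Suclg1 and Ctnna2. There were 221 adjacent rising pairs, against a mean of 142 and at most 179 in 1000 shuffles, and at most 178 when genes were also matched on exon length. Of these pairs, 194 did not overlap (at most 152 in shuffles). Without acinar list genes there were 204 (at most 175 with calls shuffled among the other genes). The 204 still held Klk1b5 beside Klk1, both outside the list with a fold and p like its members. Leaving out the list therefore did not remove every such gene. Also kept were Klk1b11 beside Klk1b3, Klk1b3 beside Klk1b4 and Klk1b4 beside Klk1b5. Prss3 beside Gm5771 and Gm5771 beside Gm10334 were kept too, and they lie between Try10 and Prss1 of the list. Leaving out acinar list genes was not combined with leaving out shared sequence or with the count of divergent pairs. Symbol stems cannot settle whether reads were shared between neighbouring paralogs, because 27 of the 197 pairs without a shared stem had 31 bases of annotated transcript in common, but shared reads are not the whole cause, since 170 pairs had neither in common (at most 153 in shuffles). Transcription running past a gene's end is not the whole cause either, since 47 pairs faced away from each other (mean 31.1 and at most 49 in shuffles, more than in 99.8% of them), while running on within a strand cannot be told apart from its absence for part of the pairs, because 47.1% were on one strand against 46.7% of all adjacent pairs (exact binomial p = 0.487, one-sided). Among the pairs, named after their values were seen, were 2310061N02Rik and Krtap13-1 beside Cldn8 on chromosome 16 (88707169 to 88707962 and 88728862 to 88729611), Cym and Prok1 on chromosome 3 (107211293 to 107221732 and 107232797 to 107239707), and Gpr26 and Cpxm2 on chromosome 7 (131966460 to 131994405 and 132032687 to 132154739).

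Ribosomal protein genes rose by a small amount as a list, with Rpl10 and Rpl5 below 0 and not passing over all genes, Rpl10 being lower adjusted over the list alone. Log2 ratios fell with exon length across genes (Spearman rho -0.175 over 15384 genes, which are not independent), with medians of 0.09 in the shortest and -0.08 in the longest of 4 bins of equal size. Exon length was merged over all annotated transcripts of a gene. A trend with the length of the transcripts present in islets was not tested and remains open. The ribosomal median of 0.38 lay above all 10000 lists matched on merged length and reads (highest 0.28), with genes taken as independent. The trend with merged exon length is therefore not the whole cause. Scaling between groups is not the whole cause either, since it shifts all genes alike and the ribosomal median stood 0.283 above the median of the matched lists, a difference that no common shift changes. Differences in RNA quality between libraries were not analysed here.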
